A study of Rattus norvegicus with 18 samples.

How the data were processed

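RNA of medullary thyroid carcinomas from 18 MENX rats was measured on Affymetrix arrays, with 6 tumours in each of 3 groups. Per the labels' protocols, total RNA was purified with RNeasy Mini kits and DNase, amplified over the whole transcript and labelled with biotin using NuGEN kits, and the animals were untreated. The values deposited by the authors are on the log2 scale and were made with RMA and Affymetrix Expression Console 1.3.0.187, per the submitters' processing notes, which do not state the order or role of each tool. Medians per array lay between 7.55 and 7.65. Arrays give no depth, and their number limits the precision.

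The value table held 29214 probe sets. The platform annotation gave 1 gene symbol for 15310 of them, several for 323 and none for 13581. Gene IDs of 15279 of the 15310 were found in a RefSeq table (GRCr8), and 0 symbols needed an update. Of 14506 genes 527 had more than 1 probe set, and the probe set with the highest mean over all arrays was used. Probe sets of the same gene differed in sign for 5 called genes of the age comparison and for 4 of the third comparison. Genes were tested where that mean reached the 30th percentile of all probe sets (6.32), which left 11370.

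The design, the alternatives, the gene lists and the rule for naming genes were set before the data were examined. Groups came from the labels. A means model of the 3 groups was fitted to all 18 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (statmod 1.5.0). The contrasts were homozygous against heterozygous tumours at 9 months, heterozygous tumours at 18 against 9 months and, as a secondary comparison, homozygous tumours at 9 against heterozygous tumours at 18 months. A gene counted as changed at a Benjamini-Hochberg adjusted p under 0.05, and a further count required a log2 change of at least 1 in size. All SEs and adjusted p-values of genes are those of limma, and all tests were two-sided except where stated.

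Gene lists numbered 40, 23 of cell programmes and 17 of cell types, with 641 of 709 entries found by name. Lists with at least 3 measured members (38 of 40) were tested with limma's camera at a preset correlation of 0.01, and also with an estimated correlation and with fry. The mean of each list per animal was compared between groups of 6 by exact permutation over all 924 assignments, adjusted over 40 lists. Intervals of differences are 95% intervals from the same permutation test. Other splits of the 12 arrays of a comparison numbered 462, of which 100 were drawn.

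The genes always named included Cdkn1b, Calca, Chga, Ret, Mki67 and Tg. Mki67 had no probe set of that name in the annotation and was not analysed here. Further genes named were the 10 largest rises and 10 largest falls among changed genes (5 and 5 in the third comparison), or the 3 with the smallest p in each direction where none changed. From each list up to 4 changed members with the smallest p were named, or the 2 members with the smallest p of a list past its threshold without changed members.

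Alternatives were no filter, a filter at the 50th percentile, the replicate number as a block, only the compared groups in the fit, eBayes with trend and robust settings, array weights, median centring, a further quantile normalization, other treatments of probe sets, list means of cell types as covariates and leaving out each array in turn. Added after the data had been seen were a variance per group, the parathyroid list mean as a covariate, means of 3 lists as covariates and leaving out homozygous replicates 1 and 3 together.

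The procedure was tested on simulated arrays of independent genes with the real means and group SDs of the 11370 genes. Changes of 0.5, 1 and 2 were called in 71.6%, 95.5% and 97.0% of cases in the genotype comparison, in 68.7%, 91.0% and 97.0% in the age comparison and in 71.6%, 91.0% and 98.5% in the third. These rates hold for 67, 67 and 66 genes changed at once at the 3 sizes. With fewer changed genes an adjusted p under 0.05 is harder to reach. The rates thus do not give the power of the real genotype comparison, which called 0 genes. Of 11142 unchanged genes 4, 20 and 58 were called. A list shifted by -0.4 was found in all 3 comparisons, and 0 of 37 other lists were called. Because the simulated genes were independent, this cannot show false list calls that come from correlated genes. The real lists were correlated, with estimates such as 0.43 for C cell and 0.70 for endothelial genes.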

Results

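Gene expression was measured in medullary thyroid carcinomas, tumours of the calcitonin-producing C cells of the thyroid, from rats of the MENX strain. MENX rats carry a mutation of Cdkn1b, the gene of the cyclin-dependent kinase inhibitor p27Kip1, and develop several kinds of neuroendocrine tumour. The 18 arrays fell into 3 groups of 6: tumours of homozygous mutants at 9 months, of heterozygous mutants at 9 months and of heterozygous mutants at 18 months. The labels give each array its own animal code, so the SDs below describe the spread between tumours of different animals. They give no sex, litter or array date, and no normal thyroid was among the samples. Values were on the log2 scale, and 11370 genes were tested. The number of arrays limits the precision of every comparison. The first principal component held 63.9% of the variance. Replicates 1, 2, 3 and 6 of the 18-month group lay between 35.8 and 69.9 on it. The 12 tumours of 9 months ranged from -28.6 to 24.0. The highest of those 12 was homozygous replicate 3, and the next highest lay at -9.68. Replicate 4 of the 18-month group lay at -11.7, among the other tumours of 9 months. Replicate 5 of that group lay at 4.21, between these and homozygous replicate 3.

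The first comparison asked how homozygous tumours differ from heterozygous ones at the same age of 9 months. Expression in the 2 groups was close, and limma called none of the 11370 genes, with 995 genes (8.75%) at an unadjusted p under 0.05 and a smallest adjusted p of 0.102. The mutated gene itself measured 11.1 ± 0.10 (SD, n = 6) in homozygous and 10.8 ± 0.10 in heterozygous tumours. All 6 homozygous values of Cdkn1b lay above every heterozygous value of that age, a difference of 0.295 (SE 0.07) with a limma adjusted p of 0.266. The part of the transcript that its probe set covers is not given in the sources used here, so this value checks no genotype. Calca, which encodes calcitonin, differed by 0.09 (SE 0.05, limma adjusted p = 0.596), and Ret, the receptor tyrosine kinase mutated in hereditary medullary carcinoma, by 0.09 (SE 0.11; 0.0515 to 0.16 without each array in turn). Chga, the granule protein chromogranin A, differed by -0.09 (SE 0.19; -0.26 to 0.0066 without each array in turn), and Tg, the thyroglobulin of follicular cells, by -0.04 (SE 0.39), or -0.022 without homozygous replicate 3. The SE of Tg comes from the spread shared by all 3 groups, which 1 tumour of the 18-month group at 11.1 widened. It does not describe the 2 groups compared, where Tg ran from 14.18 to 14.34 (homozygous) and from 14.30 to 14.37 (heterozygous). Tg measured about 14.3 in both groups, near the top of the scale (14.5 for the brightest probe set of an array on average), so a difference between them would be compressed.

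The genes with the smallest p in this comparison missed the threshold. Higher values in homozygous tumours were found for Castor2, a regulator of mTORC1 (0.42, SE 0.08), for Esrrb, an orphan nuclear receptor (0.51, SE 0.10), and for Pcsk1n, the granule protein proSAAS (0.91, SE 0.18). Lower values were found for Sv2b, a synaptic vesicle glycoprotein (-0.86, SE 0.14), for Smpd3, a neutral sphingomyelinase (-0.77, SE 0.13), and for Sh3gl3, an endophilin of endocytosis (-0.48, SE 0.08). Limma adjusted p-values of these 6 genes ranged from 0.102 to 0.118. For 5 of them all 6 homozygous tumours lay beyond every heterozygous one, and for Pcsk1n 5 of 6 did.

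By camera with a preset correlation, 11 of 38 gene lists stood apart between the genotypes, although 0 of their members passed the test over all genes. Among C cell and neuroendocrine genes 26 of 27 were higher in homozygous tumours, with a median difference of 0.41. Snap25, a protein of vesicle fusion, differed by 0.74 (SE 0.23) and the prohormone convertase Pcsk2 by 0.39 (SE 0.13). The camera adjusted p of this list was 6.54e-09, and the adjusted p = 0.467 with an estimated correlation. Without homozygous replicate 3 the difference of this list mean went from 0.42 to 0.27 and the list stayed past the threshold. Of the cell cycle list 23 of 27 genes were higher (median 0.12), with Plk1, a mitotic kinase, at 0.48 (SE 0.22) and cyclin E2 (Ccne2) at 0.56 (SE 0.27). Homozygous replicate 3 carried much of this: without it the difference of the list mean went from 0.13 to 0.018, Plk1 to 0.32 and Ccne2 to 0.34, and the list missed the threshold (limma camera adjusted p = 0.708). Of the circadian clock list 12 of 14 were higher (median 0.06), with the repressors Cry1 at 0.66 (SE 0.21) and Cry2 at 0.25 (SE 0.11). Their camera adjusted p-values of 0.0427 and 0.0488 became 0.931 and 0.757 as adjusted p with an estimated correlation.

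Of the unfolded protein response list 17 of 18 genes were lower in homozygous tumours, with a median of -0.19. Its mean was 10.7 ± 0.07 against 10.9 ± 0.19 (SD, n = 6 each). The disulfide isomerase Pdia6 differed by -0.42 (SE 0.12) and Sdf2l1, a chaperone cofactor of the endoplasmic reticulum, by -0.65 (SE 0.22). Of the oxidative phosphorylation list 26 of 28 genes were lower (median -0.12), with Ndufa4 at -0.27 (SE 0.07) and Cox7b at -0.28 (SE 0.09), and 1 gene fell adjusted over the list alone. Of the fibroblast and matrix list 17 of 19 were lower (median -0.20). Adjusted over the list alone, 4 of its genes fell and 1 rose. Lum, a collagen-binding proteoglycan, differed by -0.71 (SE 0.18) and Thy1, a surface glycoprotein of fibroblasts and neurons, by 0.38 (SE 0.11). Camera adjusted p-values of these lists were 6.3e-08, 6.54e-09 and 4.56e-05, each with an adjusted p = 0.311 with an estimated correlation.

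Also lower in homozygous tumours by camera were 5 further lists, with 19 of 19 endothelial genes (median -0.25), 9 of 10 smooth muscle and pericyte genes (-0.15), 17 of 19 skeletal muscle genes (-0.92), 5 of 5 B and plasma cell genes (-0.17) and 19 of 25 genes of receptor tyrosine kinases and their ligands (-0.11) on the lower side. Single tumours moved these differences. Without homozygous replicate 1 the difference of the endothelial list mean went from -0.24 to -0.14, that of the smooth muscle list mean from -0.19 to -0.067, Cdh5 to -0.22 and Mylk to -0.10, and both lists missed the threshold (limma camera adjusted p of 0.0861 and 0.697). Without homozygous replicate 2 the difference of the skeletal muscle list mean went from -0.73 to -0.31, and the list missed the threshold (limma camera adjusted p = 0.294), with Myh4 at -1.08 and Actn3 at -0.83. Without homozygous replicate 3 the difference of the receptor tyrosine kinase list mean went from -0.096 to -0.033 and the camera adjusted p to 0.402, that of the endothelial list mean to -0.16, that of the skeletal muscle list mean to -0.48 and Lmod1 to -0.15. Ntrk3 was at -0.16 without heterozygous replicate 3 of 9 months. The endothelial apelin receptor Aplnr differed by -0.65 (SE 0.29) and VE-cadherin (Cdh5) by -0.35 (SE 0.17). The contractile genes Lmod1 and Mylk differed by -0.25 (SE 0.11) and -0.16 (SE 0.10). The fast-muscle genes Myh4 and Actn3 differed by -1.74 (SE 1.00) and -1.35 (SE 0.84). Of the B and plasma cell list, Derl3, a factor of protein degradation, differed by -0.71 (SE 0.26) and the B cell kinase Blk by -0.14 (SE 0.06). The growth factor Igf2 and the neurotrophin receptor Ntrk3 differed by -0.22 (SE 0.07) and -0.25 (SE 0.13). Camera adjusted p-values of these 5 lists ran from 0.00346 to 0.0464. For the B and plasma cell list the adjusted p = 0.311 with an estimated correlation, and for the other 4 the adjusted p = 0.931 with an estimated correlation. Follicular genes were lower in 11 of 12 cases (median -0.27) and their list was not past the threshold (limma camera adjusted p = 0.365), and without homozygous replicate 3 the list mean difference went from -0.24 to -0.10. By comparison, 23 of 100 splits of the 12 tumours into 6 and 6, the real one included, gave at least 11 lists. None of 40 list means per animal differed by exact permutation after adjustment, and 6 had an unadjusted p under 0.05.

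The spread in this model was shared with the 18-month group, which varied most. With only the 2 groups in the fit 24 genes passed (4 higher, 20 lower), with array weights 118 passed (68 higher, 50 lower), and leaving out homozygous replicate 1, homozygous replicate 3 or heterozygous replicate 1 of 9 months left 7 lists past the threshold. Without each array in turn 4 of the 11 lists always passed, those of C cell, oxidative phosphorylation, unfolded protein response and fibroblast genes. With an estimated correlation none of these 4 passed (adjusted p = 0.467 for the C cell list and adjusted p = 0.311 for the others with an estimated correlation), and with fry 0 lists passed.

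**Figure D1:**
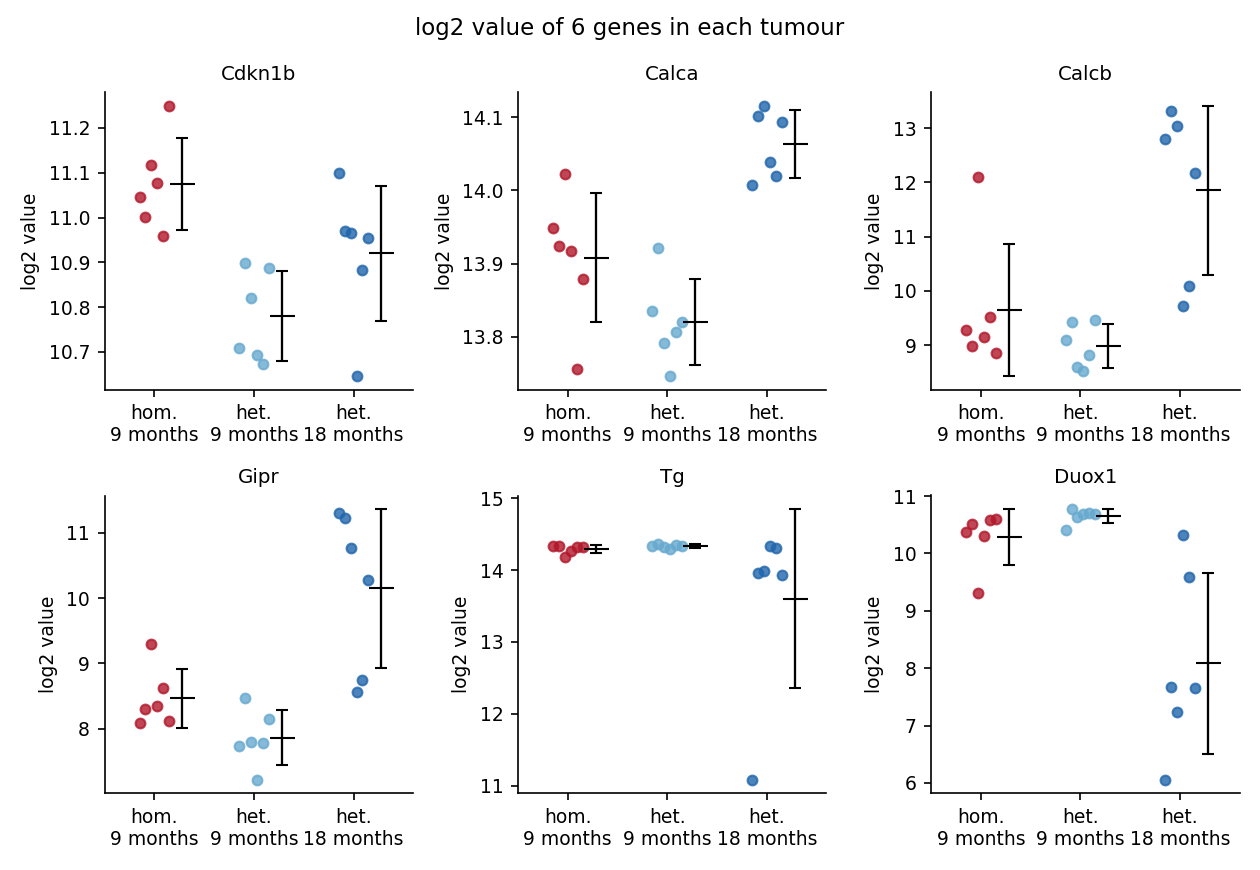
log2 values (y axis) of 6 genes in each tumour, in homozygous rats at 9 months and heterozygous rats at 9 and 18 months. Points are animals, and bars to their right give the mean ± SD, n = 6 per group. Calcb lies between 12.2 and 13.3 in 4 of the 18-month tumours and at 9.72 and 10.1 in the others.

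The second comparison asked what differs between heterozygous tumours at 18 and at 9 months. At 18 months 2458 genes were higher and 2551 lower by limma, 44.1% of the 11370 genes tested, and 915 of these changed by a log2 value of 1 or more (444 up, 471 down). Calca rose by 0.24 (SE 0.05), from 13.8 ± 0.06 to 14.1 ± 0.05 (SD, n = 6 each), with all 6 older tumours above every younger one (limma adjusted p = 0.00112). Calca lay on average only 0.53 below the brightest probe set of its array, so its range upwards was short. Its paralogue Calcb, which encodes the beta form of calcitonin gene-related peptide, rose by 2.87 (SE 0.63, limma adjusted p = 0.00204).

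Of the 27 measured genes of the C cell and neuroendocrine list 21 rose, 1 fell and 5 did not pass (22 and 1 adjusted over the list alone). Chromogranin B (Chgb) rose by 1.18 (SE 0.18), Pcsk2 by 0.86 (SE 0.13), its chaperone Scg5 by 0.88 (SE 0.14) and the forkhead factor Foxa2 by 1.57 (SE 0.26), each in 6 of 6 animals. The gene that fell, chosen after its values were seen, was Nkx2-1, a transcription factor of both C cells and follicular cells (-0.37, SE 0.10). Ret differed by 0.06 (SE 0.11, limma adjusted p = 0.676) and Chga by -0.14 (SE 0.19, adjusted p = 0.59). Without each array in turn Ret ranged from -0.0079 to 0.13 and Chga from -0.31 to -0.043. Chga varied along with Gcm2, the transcription factor of the parathyroid. In both 9-month groups the tumours lowest and highest for Chga were also lowest and highest for Gcm2. At 18 months this held for the highest (13.1 in replicate 4) and not for the lowest. With the parathyroid list mean as a covariate Chga differed by 0.18 (limma adjusted p = 0.425), so its change within the tumour cells is not known. The list mean was 11.3 ± 0.40 at 18 months and 10.2 ± 0.21 at 9 months, with an exact permutation p of 0.00216, the smallest that 924 assignments allow (adjusted p = 0.0144). The list was also past the threshold of limma's camera (adjusted p = 5.79e-08), with an adjusted p = 0.831 with an estimated correlation.

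Among the 10 largest rises were, besides Calcb, 9 other genes. Cbln4, a secreted synapse organiser, rose by 3.67 (SE 0.84), Gabra3, a subunit of the GABA-A receptor, by 2.73 (SE 0.76), Gad2, an enzyme of GABA synthesis, by 2.61 (SE 0.84) and Scn3b, a sodium channel subunit, by 2.52 (SE 0.78). Bcat1, an aminotransferase of branched-chain amino acids, rose by 2.62, the Ras exchange factor Rasgrf1 by 2.52, Rab6b, a GTPase of Golgi transport in neurons, by 2.49, Ankrd34c by 2.37 and the zinc finger gene Zcchc12 by 2.30. Limma adjusted p-values of these 9 genes ran from 0.0015 to 0.0189, and Gad2 lost its call without replicate 2 of the 18-month group. Cbln4 measured 11.2 or more in 4 of the 18-month tumours and 7.40 and 7.73 in replicates 4 and 5.

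Of 12 measured follicular genes 10 fell and 2 did not pass (10 fell and 1 rose adjusted over the list alone). Falls were measured for Duox1, an oxidase that supplies hydrogen peroxide for hormone synthesis (-2.56, SE 0.52), its maturation factor Duoxa1 (-1.82, SE 0.35), the thyrotropin receptor Tshr (-1.99, SE 0.46) and the deiodinase Iyd (-2.42, SE 0.57). All 6 older tumours lay below every younger one for each of these 4 genes. Tg differed by -0.73 (SE 0.39, limma adjusted p = 0.136), with 1 tumour at 11.1 and the other 5 between 13.9 and 14.3. Without that tumour the difference was -0.23 and Tg passed the threshold. Its 9-month values lay near the top of the scale, so this difference is compressed and its size is not measured. The list mean was 9.93 ± 1.35 at 18 months and 11.6 ± 0.05 at 9 months (exact permutation p = 0.00216, adjusted p = 0.0144; camera adjusted p = 0.00258, and adjusted p = 0.831 with an estimated correlation). Replicates 4 and 5 of the 18-month group measured 11.4 and 11.2, against 7.71 to 9.92 in the other 4.

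Of 19 endothelial genes 17 fell, 1 rose and 1 did not pass (18 and 1 adjusted over the list alone). The list mean was 9.42 and 9.21 in replicates 4 and 5 of the 18-month group, against 7.88 to 8.55 in the others of that group. Among those that fell were Esm1, a proteoglycan of tip cells (-1.37, SE 0.28), the adhesion molecule Pecam1 (-1.09, SE 0.25), Cdh5 (-0.78, SE 0.17) and the arterial factor Sox17 (-0.57, SE 0.13). The gene that rose, chosen after its values were seen, was Angpt2, a destabilising ligand of the Tie2 receptor (0.40, SE 0.11). Of 11 adipocyte genes 10 fell, also adjusted over the list alone. They included the lipase genes Lipe (-0.87, SE 0.24) and Lpl (-0.90, SE 0.27), the adipokine gene Adipoq (-1.51, SE 0.42) and Cfd, complement factor D (-0.65, SE 0.20). Of 7 mast cell genes 4 fell, also adjusted over the list alone, among them the proteases Cpa3 (-1.33, SE 0.25) and Cma1 (-0.97, SE 0.21). The mast cell list mean differed by exact permutation (adjusted p = 0.0433) and the list was not past the camera threshold (adjusted p = 0.238).

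Of 25 genes of receptor tyrosine kinases and ligands 15 fell, 1 rose and 9 did not pass (16 and 1 adjusted over the list alone). Replicates 4 and 5 of the 18-month group again stood apart, with list means of 8.74 and 8.56 against 7.85 to 8.31 in the others. Lower values were measured for Pdgfra, the alpha receptor of platelet-derived growth factor (-1.14, SE 0.21), Met, the receptor of hepatocyte growth factor (-1.19, SE 0.23), the epidermal growth factor receptor Egfr (-0.50, SE 0.11) and Vegfa, the main growth factor of vessels (-0.99, SE 0.20). Of 24 interferon response genes 6 fell and 2 rose, also adjusted over the list alone. The falls included the antiviral GTPase Mx1 (-1.34, SE 0.23), the signal transducer Stat2 (-1.08, SE 0.22), Ifih1, a sensor of viral RNA (-0.90, SE 0.23), and the antiviral protein Bst2 (-0.57, SE 0.14). Of 28 ribosomal protein genes 8 fell and 20 did not pass, also adjusted over the list alone, with Rps19 at -0.49 (SE 0.07), Rpl7 at -0.44 (SE 0.08), Rps14 at -0.34 (SE 0.08) and Rpl10a at -0.33 (SE 0.06).

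**Figure D2:**
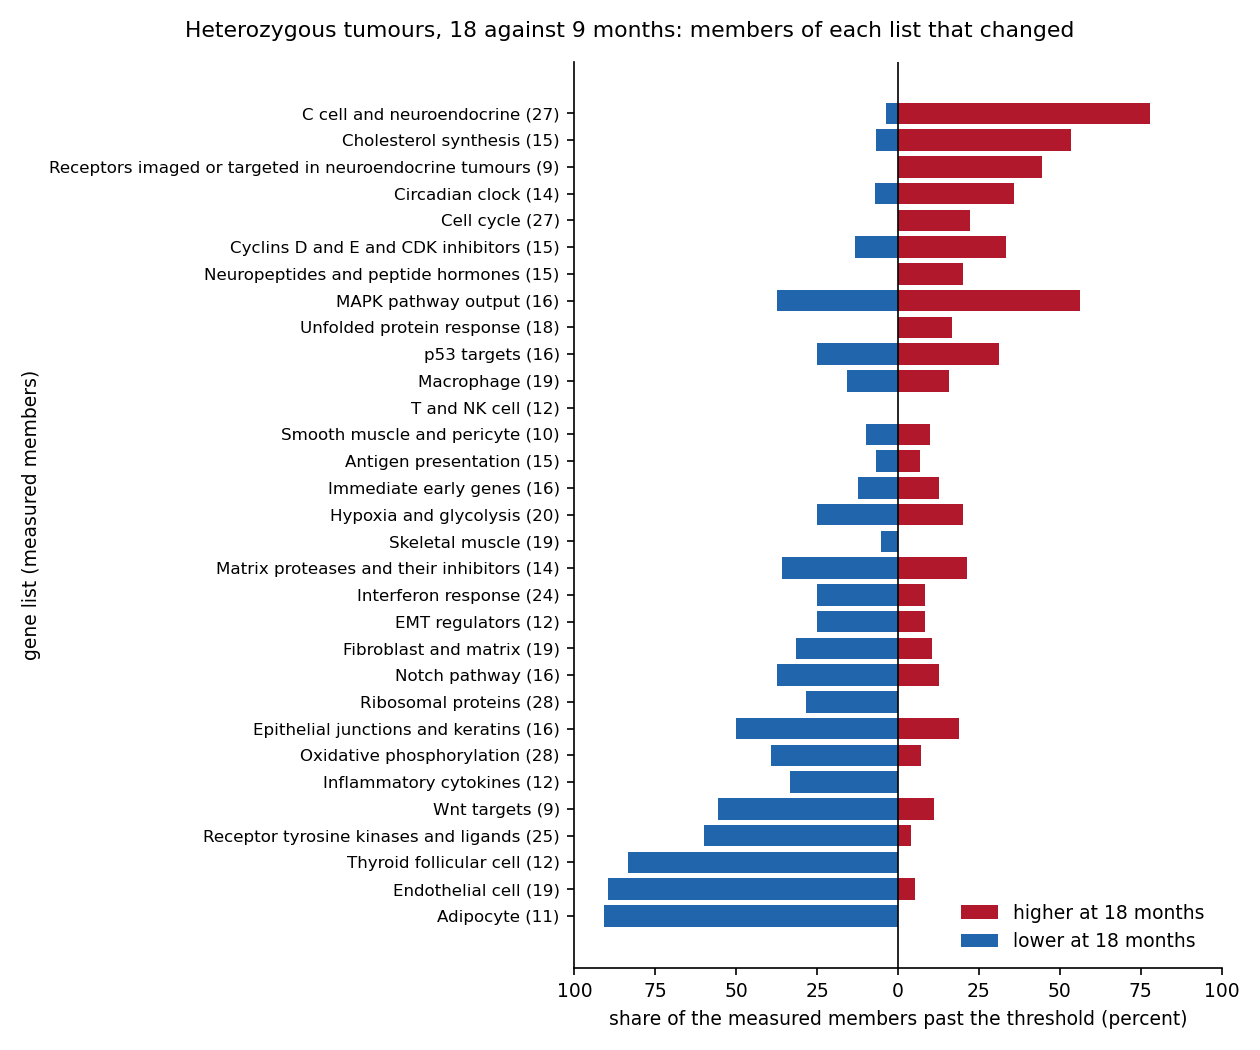
Share of the measured members of each gene list (y axis, measured members in parentheses) that were higher or lower at 18 than at 9 months in heterozygous tumours (x axis, percent). Lists with at least 9 measured members are drawn. The C cell list stands at the top with 21 of 27 genes higher, and the adipocyte list at the bottom with 10 of 11 lower.

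Of 9 receptors imaged or targeted in neuroendocrine tumours 4 rose, also adjusted over the list alone: the incretin receptors Gipr (2.28, SE 0.42) and Glp1r (1.58, SE 0.39), the somatostatin receptor Sstr4 (0.20, SE 0.06) and Vipr1, a receptor of vasoactive intestinal peptide (0.50, SE 0.16). Of 15 cholesterol synthesis genes 8 rose and 1 fell, also adjusted over the list alone, with Sc5d at 0.62 (SE 0.13), Dhcr7 at 0.54 (SE 0.13), Lss at 0.52 (SE 0.11) and Fdps at 0.36 (SE 0.07). Of 14 circadian clock genes 5 rose and 1 fell (4 and 1 adjusted over the list alone). The repressors Bhlhe41, Per2 and Cry2 rose by 1.42 (SE 0.23), 1.00 (SE 0.19) and 0.62 (SE 0.11), and the activator Npas2 fell by 1.17 (SE 0.20). The means of these 3 lists differed by exact permutation (adjusted p of 0.0144, 0.0216 and 0.0144), and none was past the camera threshold (adjusted p of 0.15, 0.0507 and 0.0698).

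Of 27 cell cycle genes 6 rose and 21 did not pass, and 1 rose adjusted over the list alone. Ccne2 rose by 1.13 (SE 0.27), Plk1 by 0.67 (SE 0.22), the spindle protein Prc1 by 0.69 (SE 0.26) and cyclin B2 (Ccnb2) by 0.39 (SE 0.13). Of these Plk1, Prc1 and Ccnb2 lost their call without replicate 1 of the 18-month group, and Plk1 and Prc1 also without replicate 4 of the younger group. Prc1 further lost its call without replicate 1, 2 or 3 of the younger group or replicate 3 of the older group. Of 15 cyclins, kinases and inhibitors of the G1 phase 5 rose and 2 fell, also adjusted over the list alone. Cyclin D3 (Ccnd3) rose by 0.39 (SE 0.08) and Skp2, the ubiquitin ligase subunit that targets p27Kip1, by 0.48 (SE 0.10). The kinase Cdk2, which p27Kip1 inhibits, fell by 0.89 (SE 0.19). Cdkn1b differed by 0.14 (SE 0.07, limma adjusted p = 0.126).

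The other large falls were those of Cxcl13, a B cell chemokine (-2.49, SE 0.40), the desmosomal cadherin Dsc3 (-2.89, SE 0.59), the potassium channel Kcnj16 (-2.43, SE 0.58), the tendon gene Tnmd (-2.60, SE 0.85) and Myh4 (-2.73, SE 1.00). They further included Rhcg, an ammonia transporter (-2.91, SE 1.07), Sostdc1, an antagonist of BMP and Wnt signals (-2.68, SE 0.89), and Gcm2, the transcription factor of the parathyroid (-2.58, SE 1.01, limma adjusted p = 0.0468). Without replicate 4 of the 9-month group Myh4, Rhcg, Sostdc1 and Gcm2 lost their calls, and Myh4, Rhcg and Gcm2 also without several other single arrays. Rhcg, Sostdc1, Gcm2 and Tnmd were each lowest within the 9-month group in replicate 1 and highest within the 18-month group in replicate 4. Markers of neighbouring tissue varied between tumours: the parathyroid list mean ran from 9.87 to 12.8 at 9 months and from 8.53 to 12.9 at 18 months, and the skeletal muscle list mean from 8.86 to 10.8 and from 6.82 to 10.3. Of 3 parathyroid genes Gcm2 fell and Casr, the calcium-sensing receptor that C cells also express, rose by 0.56 (2 fell and 1 rose adjusted over the list alone). Of 19 skeletal muscle genes only Myh4 fell, and 0 passed adjusted over the list alone.

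By camera 7 lists were past the threshold at 18 months, namely C cell, follicular, endothelial, adipocyte, receptor tyrosine kinase, interferon and ribosomal genes, and for each of the 7 the adjusted p = 0.831 with an estimated correlation. Splits of the 12 tumours gave at least 7 lists in 79 of 100 cases, the real split included. Interferon genes missed the threshold of limma camera without replicate 2 of the 9-month group (adjusted p = 0.051). With the follicular list mean as a covariate 210 genes passed and with means of the skeletal muscle and adipocyte lists 490 passed. Without replicate 2, 4, 5 or 6 of the 9-month group 0 of the 10 list means stayed past the exact permutation threshold. Leaving out 1 tumour leaves fewer assignments and coarser p-values. The differences of the C cell, follicular and endothelial list means stayed about as large without each of these tumours. The adipocyte list mean was not among the 10 (exact permutation adjusted p = 0.0666).

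**Figure D3:**
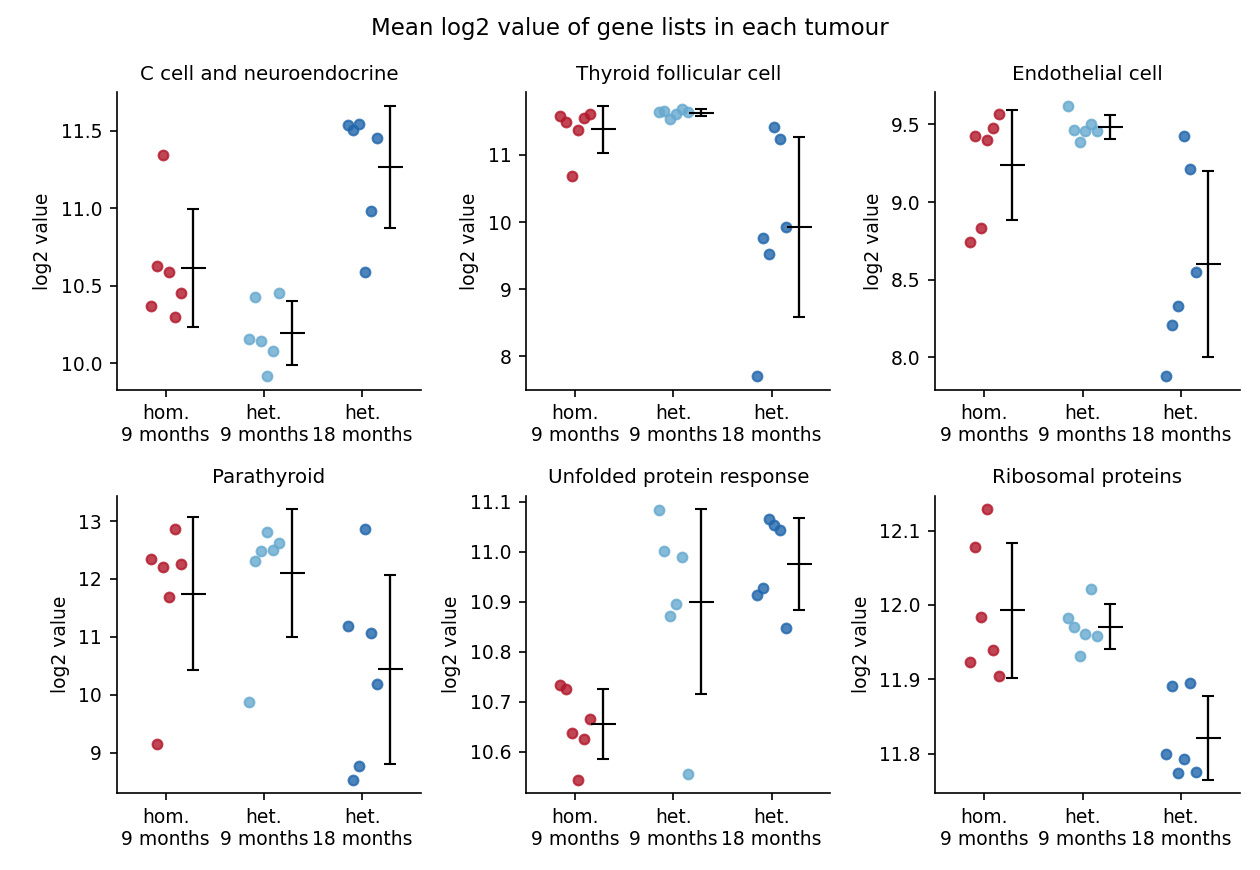
Mean log2 value (y axis) of 6 gene lists in each tumour, in homozygous rats at 9 months and heterozygous rats at 9 and 18 months. Points are animals, and bars to their right give the mean ± SD, n = 6 per group. In the 18-month group replicates 4 and 5 lie at 11.4 and 11.2 for the follicular list, close to the 9-month tumours.

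The third comparison set homozygous tumours at 9 months against heterozygous tumours at 18 months, which differ in genotype and in age. In homozygous tumours 1846 genes were higher and 1546 lower by limma, and 456 of these differed by a log2 value of 1 or more (300 higher, 156 lower). Calca fell below the older tumours, with a difference of -0.155 (SE 0.05, limma adjusted p = 0.0231), while Cdkn1b (0.16, SE 0.07), Tg (0.69, SE 0.39), Ret (0.03, SE 0.11) and Chga (0.05, SE 0.19) did not pass. Tg, near the top of the scale at 9 months, differed by 0.19 without replicate 1 of the 18-month group, and Cdkn1b by 0.10 without replicate 4. Without each array in turn Ret ranged from -0.037 to 0.099 and Chga from -0.041 to 0.17.

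Of 18 unfolded protein response genes 8 were lower and 10 did not pass, also adjusted over the list alone. The lower genes included the chaperone Hyou1 (-0.73, SE 0.11), the cofactor Dnajb9 (-0.77, SE 0.14), Pdia6 (-0.53, SE 0.12) and Asns, the asparagine synthetase (-0.48, SE 0.11). The list mean was 10.66 ± 0.07 in homozygous and 10.98 ± 0.09 in heterozygous tumours, with no overlap between the 6 and 6 animals (exact permutation p = 0.00216, adjusted p = 0.0433). Of 28 ribosomal protein genes 11 were higher (12 adjusted over the list alone), with Rpl7 at 0.45 (SE 0.08), Rps14 at 0.38 (SE 0.08), Rps19 at 0.37 (SE 0.07) and Rpl10a at 0.33 (SE 0.06). Their list mean was 11.99 ± 0.09 against 11.82 ± 0.06 (exact permutation adjusted p = 0.0433). Means of the other 38 lists did not pass that test.

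Of 27 C cell and neuroendocrine genes 16 were lower and 1 higher (19 and 1 adjusted over the list alone), among them the carboxypeptidase Cpe (-1.09, SE 0.26), the secretogranin Scg3 (-0.90, SE 0.23) and Chgb (-0.68, SE 0.18). The higher gene was Nkx2-1 (0.43, SE 0.10). Of 12 follicular genes 8 were higher (10 adjusted over the list alone), such as Tshr (1.86, SE 0.46) and Duoxa1 (1.47, SE 0.35). Of 19 endothelial genes 9 were higher and 1 lower (14 and 1 adjusted over the list alone). Plvap, a component of fenestrations, was higher by 1.19 (SE 0.35), the receptor Tek by 0.97 (SE 0.29) and Esm1 by 0.95 (SE 0.28), and Angpt2 was lower (-0.44, SE 0.11). Of 11 adipocyte genes 3 were higher (6 adjusted over the list alone): Adipoq (1.16, SE 0.42), Cidec (0.86, SE 0.29) and Lpl (0.79, SE 0.27).

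Of 25 genes of receptor tyrosine kinases and ligands 11 were higher, also adjusted over the list alone. Erbb3 was higher by 1.55 (SE 0.32), its partner Erbb2 by 0.84 (SE 0.21), Vegfa by 0.85 (SE 0.20) and Pdgfra by 0.84 (SE 0.21). Of 24 interferon response genes 4 were higher and 1 lower, also adjusted over the list alone, with Mx1 at 1.00 (SE 0.23), Stat2 at 0.74 (SE 0.22), Ifih1 at 0.71 (SE 0.23) and Bst2 at 0.45 (SE 0.14). Of 15 genes of cyclins, kinases and inhibitors 1 was higher and 4 lower (2 and 5 adjusted over the list alone). Cdk2 was higher by 0.98 (SE 0.19), and the D-type cyclins Ccnd1 (-1.08, SE 0.27), Ccnd2 (-1.04, SE 0.21) and Ccnd3 (-0.37, SE 0.08) were lower. The largest differences were those of Cbln4 (-2.94, SE 0.84), Gabra3 (-2.53, SE 0.76), the receptor gene Adgrg7 (-2.30, SE 0.42), Calcb (-2.21, SE 0.63) and Rasgrf1 (-2.09, SE 0.65) on the lower side. On the higher side they were the phospholipase Pla2g10 (2.21, SE 0.39), Duox1 (2.19, SE 0.52), Kcnj16 (2.17, SE 0.58), Iyd (2.11, SE 0.57) and Nsun7 (2.03, SE 0.54).

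By camera 8 lists were past the threshold, the 7 of the age comparison and the unfolded protein response, with an adjusted p = 0.904 with an estimated correlation for interferon genes and an adjusted p = 0.784 with an estimated correlation for the other 7. At least 8 lists were given by 72 of 100 splits of the 12 tumours, the real one included. The spread of the main fit was shared with the 9-month heterozygous group, which varied least (median SD 0.107 against 0.160 and 0.191). In the simulated arrays this comparison gave a share of false calls above 0.05. With only the 2 groups in the fit 708 genes passed, with the follicular list mean as a covariate 4, with means of the muscle and adipocyte lists 2, and without replicate 2 of the 18-month group 2116. Without that tumour Calca, Gabra3, Rasgrf1, Plvap, Tek, Esm1, Adipoq, Cidec, Lpl, Stat2, Ifih1 and Bst2 lost their calls, although each kept its direction, with mostly somewhat smaller differences. The interferon list then missed the threshold (limma camera adjusted p = 0.0504), as it did without homozygous replicate 5 or 6 (0.105 and 0.133). The 2 list means also missed their threshold without each of 7 single arrays. An example is replicate 1 of the 18-month group (exact permutation adjusted p = 0.0866 each). Fewer assignments and coarser p-values then remain, so these lost calls do not by themselves show smaller differences. Over these 7 fits the difference of the unfolded protein response list mean lay between -0.345 and -0.298, against -0.320 with all arrays. That of the ribosomal list mean lay between 0.144 and 0.186, against 0.172.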

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

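Tests on the age pattern and on the unfolded protein response were chosen after those results were seen, and the reading of the position test was made stricter after its values were known. Within groups of 6 tumours, 38 of 379 sets of values had a lowest or highest value far from the rest by Dixon's test. Chance alone sets apart about 1 in 20 groups. Of the 38, 16 lay in homozygous replicate 3, 6 each in replicate 1 of the heterozygous tumours of 9 months and replicate 4 of those of 18 months, and 10 in other tumours.

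Homozygous replicate 3 stood above the other 5 homozygous tumours for Calcb (12.1), Ccnd1 (11.01), Ccnd3 (10.3), Ccne2 (8.62), Plk1 (8.22) and the C cell list mean (11.3). It stood below them for Duox1 (9.31), Duoxa1 (8.92), Erbb2 (8.22), Erbb3 (8.6), Iyd (11.3), Nsun7 (9.1), Pla2g10 (8.71), Stat2 (10.003), Vegfa (11.4) and the follicular list mean (10.7). Homozygous replicate 4 was highest for Lum (9.91).

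Replicate 1 of the 9-month heterozygous group was lowest for Duox1 (10.4), Gcm2 (6.29), Rhcg (7.07), Sostdc1 (7.1), the circadian list mean (9.5) and the parathyroid list mean (9.87). Replicate 2 was highest for Ankrd34c (7.4), Gabra3 (6.45) and Rab6b (7.3), and replicate 3 for Ntrk3 (7.77). Replicate 5 was lowest for Phlda1 (9.31) and replicate 4 for Plk1 (6.42). In the 18-month group replicate 4 was highest for Chga (13.1), Gcm2 (11.2), Rhcg (11.7), Sostdc1 (11.1), Tnmd (9.06) and the mesenchymal transcription factor Twist1 (8.31). Replicate 1 of that group was lowest for Tg (11.1) and highest for Prc1 (8.68) and the cell cycle list mean (8.26).

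The first pattern was the higher C cell and lower follicular genes at 18 months. The test took it that a smaller share of follicular cells as the whole cause would raise the markers of every other cell type. The endothelial list mean fell, with an upper 95% bound of -0.249. It was highest at 18 months in replicates 4 and 5 (9.42 and 9.21), where the follicular list mean was also highest. If vessels were lost along with follicles, both would fall, so the test could not decide on this cause. A larger share of C cells as the whole cause of the higher C cell genes was tested on Ret and Gfra4. Their mean changed by 0.138 (95% interval -0.398 to 0.665), against a median change of 1.18 for the other 25 C cell genes. The whole interval lay below 1.18, so this pair rose less than the typical C cell gene. A decision against the cause required an upper bound below a set fraction of 1.18, which was not met, so it stayed open. For the follicular genes themselves, fewer such cells may be the cause, since 10 of 11 other than Tg had intervals below 0 and 0 lay above it, although Hhex differed by 0.47. Changes with age within the tumour cells and differences in collection between the age groups were not tested.

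The second pattern was the lower unfolded protein response list in homozygous tumours. The array with the narrowest spread of values, homozygous replicate 1, was not its source, since the list had a camera adjusted p of 1.39e-07 without it. With all arrays the call was lost with an estimated correlation (adjusted p = 0.311 with an estimated correlation) and with fry (0.116), and the list mean had an exact permutation adjusted p of 0.173. Fewer follicular cells were tested on the heterozygous tumours of 18 months, where the follicular list fell. Their unfolded protein response list mean differed from that at 9 months by 0.08. Its lower bound of -0.0909 lay above the genotype difference of -0.245. But 3 genes of the list rose with age, and a rise with age could hide a fall, so this cause was not decided. The genotype itself and differences in tissue handling stayed open and untested.

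The third pattern was the place of homozygous replicate 3 near the 18-month tumours. On 50 genes chosen without it, its position between heterozygous (0) and homozygous (1) tumours was 0.0265. The genes were chosen against both heterozygous ages together. A low position can thus mark likeness to the 18-month tumours and does not tell the genotype. Its unfolded protein response list mean (10.64) lay below every 18-month tumour (lowest 10.85). Its ribosomal list mean (11.98) lay above every one (highest 11.90). Both lists were picked from a comparison that included this tumour, so whether a heterozygous animal was its source stayed open. Other homozygous tumours ranged from 0.363 to 1.19 and heterozygous tumours of 9 months from 0.369 to 0.764, so the position separated the genotypes poorly. The highest position in the 18-month group was 0.384. That lay under the bound of 0.5 set against an exchange of labels, but so did homozygous replicate 1, and the bound decided nothing. Whether this tumour was more advanced than others of its age was not tested.

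Of 100 splits of each comparison's arrays, the real one included, 1 reached the count of genes with age (5009, highest other 4438). In the third comparison 3 splits reached the real count of 3392, and 2 of them exceeded it (highest 4506). So few splits make chance alone an unlikely source of these counts, but with 100 of 462 splits drawn it was not excluded. For the genotype comparison the count decided nothing, since the real count was 0 and all 100 splits had to reach it (highest other 0). For lists past camera the real counts did not stand out. At least the 11 of the genotype comparison came from 23 splits (highest 16). At least the 7 of the age comparison came from 79 (highest 17), and at least the 8 of the third from 72 (highest 19).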

How the results depend on the processing

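Fits with a variance per group, the parathyroid covariate, 3 covariates and without 2 homozygous arrays together were chosen after results were seen. The planned covariate for sex was not run, because Xist, Ddx3y, Kdm5d and Eif2s3y are not named on the array. Of 103 named genes changed with age 98 kept their direction in every alternative, 100 their call in those without covariates and with all arrays, and 95 without each array in turn. Of 44 named genes changed in the third comparison all 44 kept their direction, 16 and 32 their calls. Where no cause is given below, the cause was not tested.

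In the genotype comparison, changed genes rose from 0 to 24 with only the 2 groups compared, 118 with arrayWeights, 25 with a variance per group, 6 with the follicular list mean as covariate and 2 with 3 covariates. Without each array in turn there were 0 to 2, with 2 without replicate 4 of the 18-month group. Other alternatives gave 0. Tg turned to 0.14 with the follicular covariate and 0.13 with 3 covariates, and without each array Chga ranged from -0.26 to 0.0066 and Ret from 0.0515 to 0.16. The 11 lists became 0 with an estimated correlation, 0 with fry, 7 with the follicular covariate and 7 without homozygous replicates 1 and 3, and ranged from 7 to 12 without each array. The follicular list turned direction with its own mean as covariate (camera adjusted p = 0.922). In every comparison this covariate removes the mean difference of that list by construction, so the direction of the list under it tells nothing. Tg is a member of the list, so its turns with this covariate are limited in the same way.

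In the age comparison, the 5009 genes became 915 at a log2 change of 1 or more, 210 with the follicular covariate (188 of them among the 5009), 490 with muscle and adipocyte covariates, 2925 with the parathyroid covariate and 3 with 3 covariates. The follicular list itself fell with age, so its covariate takes up part of the age difference by construction. Of the 103 named genes 4, 18, 81 and 0 kept their call in these 4 fits. Signs turned with the follicular covariate for Cdkn1b (-0.019), Tg (0.58), Chga (0.13), Prc1 (-0.0035) and Hey2 (0.018). With muscle and adipocyte covariates they turned for Chga (0.088) and Ret (-0.036), and with the parathyroid covariate for Chga (0.18). With 3 covariates they turned for Tg (0.49), Chga (0.32), Sostdc1 (0.18), Gcm2 (0.36), Timp3 (0.038) and Hey2 (0.044). Ret was -0.0018 with arrayWeights. Without each array Ret ranged from -0.0079 to 0.13 and Chga from -0.31 to -0.043.

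Lists past the threshold with age went from 7 to 0 with an estimated correlation, 11 with fry and 11 with no filter. The direction turned with the follicular covariate for follicular (adjusted p = 0.928), cell cycle (0.0907) and parathyroid lists (0.915). The parathyroid list also turned with fry (0.939), without homozygous replicates 1 and 3 (0.943) and in 5 of the fits without a single array. Its adjusted p ranged from 0.773 to 0.999 without each array. List means that differ, 10 with all arrays, ranged from 0 to 17 without each array. Leaving out 1 array leaves fewer assignments and coarser p-values, which can end calls at differences of similar size. Other causes were not tested. The mean of cyclins and inhibitors turned to -0.19 as a median of the members.

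In the third comparison, the 3392 genes became 456 at a log2 change of 1 or more, 708 with only the 2 groups compared, 4 with the follicular covariate, 2 with muscle and adipocyte covariates, 751 with the parathyroid covariate and 0 with 3 covariates (1156 at an unadjusted p under 0.05). Without each array they ranged from 2116 to 4702. Signs turned with the follicular covariate for Tg (-0.44), Chga (-0.18) and Ret (-0.095), and with 3 covariates for Tg (-0.36), Chga (-0.32) and Ret (-0.036). Chga was -0.13 with muscle and adipocyte covariates and -0.202 with the parathyroid covariate. Without each array Chga ranged from -0.041 to 0.17 and Ret from -0.037 to 0.099. The 8 lists became 0 with an estimated correlation, and follicular (0.981) and endothelial lists (0.874) turned with the follicular covariate. List means that differ went from 2 to 0 as a median of the members and 0 with each array's median subtracted. They ranged from 0 to 10 without each array, where fewer assignments made p-values coarser.

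The labels do not tie replicate numbers across groups. Correlations of deviations between tumours of the same number ran from -0.139 to 0.301 between genotypes, from -0.127 to 0.327 between ages (4 of 6 at 0.155 or more) and from -0.288 to 0.353 in the third comparison. The own number correlated best for 1, 3 and 0 of 6 numbers, so not for every tumour in any comparison. With the number as a replicate block the counts of genes were 0, 4866 and 3433, those of lists 11, 9 and 10, and those of list means 0, 0 and 0. For list means 6 numbers allow 64 sign changes and no p under 0.0312, so 26 of 40 lists would have to reach it for any to pass after adjustment. Of the named genes Myh4 lost its age call (adjusted p = 0.0511). Cholesterol (0.0378) and circadian lists (0.034) passed with age, each with an adjusted p = 0.831 with an estimated correlation in the fit without the replicate block.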

Other observations

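The gene families and the comparison of directions were chosen only after results were seen. Several programmes changed at 18 months in both directions. Of 16 MAPK output genes 9 rose and 6 fell, with the feedback inhibitors Spry4 (0.57, SE 0.13) and Spred2 (0.36, SE 0.09) up and Spry2 (-0.55, SE 0.13) and Phlda1 (-0.78, SE 0.17) down. Of 16 p53 targets 5 rose and 4 fell, among them Zmat3, an RNA-binding tumour suppressor (1.05, SE 0.19), and Perp, a junction protein (-1.40, SE 0.33). Of 16 Notch genes 2 rose and 6 fell, with the ligands Jag2 (0.65, SE 0.10) and Dll1 (0.46, SE 0.14) up and Notch2 (-0.91, SE 0.20) and the effector Hey2 (-0.91, SE 0.27) down. Of 14 matrix proteases and inhibitors 3 rose and 5 fell: the macrophage elastase Mmp12 rose by 2.16 (SE 0.55), while the urokinase Plau (-1.03, SE 0.20), Timp3 (-0.98, SE 0.26) and Mmp2 (-0.41, SE 0.11) were lower. Of 12 EMT regulators 1 rose, N-cadherin (Cdh2, 1.71, SE 0.45), and 3 fell: Prrx1 (-0.60, SE 0.14), Zeb2 (-0.61, SE 0.15) and Twist1 (-0.63, SE 0.19). These counts were the same adjusted over the list alone.

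Of 28 oxidative phosphorylation genes 2 rose and 11 fell, led by Sdha (-0.61, SE 0.09), Uqcrc2 (-0.27, SE 0.06), Sdhd (-0.36, SE 0.08) and Atp5f1a (-0.23, SE 0.05). Of 18 unfolded protein response genes 3 rose: Hyou1 (0.55, SE 0.11), Asns (0.50, SE 0.11) and Dnajb9 (0.56, SE 0.14). Of 19 macrophage genes 3 rose, the complement genes C1qa (0.53, SE 0.15), C1qb (0.67, SE 0.19) and C1qc (0.48, SE 0.14), and 3 fell, among them Adgre1 (-0.69, SE 0.14). Of 19 fibroblast genes 2 rose, among them Thy1 (0.68, SE 0.11), and 6 fell, among them Lum (-0.94, SE 0.18) and Fstl1 (-0.59, SE 0.11). Of 15 neuropeptide genes 3 rose (2 adjusted over the list alone), among them adrenomedullin (Adm, 0.94, SE 0.14) and Cartpt (1.32, SE 0.37). In the other lists of this paragraph the counts were the same adjusted over the list alone.

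Among the other lists epithelial junctions and keratins had 3 rises and 8 falls of 16, Wnt targets 1 and 5 of 9, hypoxia and glycolysis 4 and 5 of 20, and inflammatory cytokines 0 and 4 of 12 at 18 months, also adjusted over the list alone. Immediate early genes had 2 rises and 2 falls of 16 (2 and 1 adjusted over the list alone), antigen presentation 1 and 1 of 15 (0 adjusted over the list alone), and Schwann cell genes 0 and 2 of 4 (1 and 2 adjusted over the list alone). Smooth muscle genes had 1 rise and 1 fall of 10, B and plasma cell genes 1 fall of 5, and the single thymocyte gene fell, also adjusted over the list alone. No member changed by limma among 12 T and NK cell, 8 cartilage, 8 airway, 5 erythroid genes and 1 neutrophil gene. None of the lists described so far in this part passed camera with age, and lists with fewer than 3 measured members were not tested by it. In the genotype comparison 1 of 15 cyclins and inhibitors rose adjusted over the list alone.

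Among gene families at 18 months, 6 of 8 voltage-gated sodium channels rose (camera adjusted p = 0.0206), 12 of 23 calcium channels rose and 1 fell (0.00223), and 9 of 14 synaptotagmins rose (0.00395). With an estimated correlation these adjusted p-values were 0.259, 0.243 and 0.243. Of 8 GABA-A receptor subunits 4 rose and 1 fell (camera adjusted p = 0.131), of 67 potassium channels 22 rose and 8 fell (0.108), of 16 claudins 2 rose and 10 fell (0.0686), and of 6 desmosomal genes 3 fell (0.082). For these 4 families the adjusted p-values with an estimated correlation were 0.243, 0.243, 0.262 and 0.262.

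Alleles of the founder strains linked to the mutated gene were tested around Cdkn1b on chromosome 4. Of the 50 nearest tested genes 5 had an unadjusted p under 0.05 between genotypes, against 942 of 10719 on other chromosomes (one-sided Fisher exact p = 0.452). No excess was found.

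Homozygous tumours at 9 months may differ from heterozygous ones in the direction of the 18-month tumours. With the 9-month heterozygous arrays split so that none was shared, the 2 sets of differences correlated at 0.641 over 11370 genes, which are not independent replicates. Of 100 random reassignments of the arrays 0 reached this, with a highest of 0.628 and a 95th percentile of 0.51. Without homozygous replicate 3 the correlation with split arrays was 0.397 and the covariance 0.0356. A correlation of 0.397 was reached by 14 of 100 reassignments, but these drew on all 18 arrays, that tumour included. Reassignments without it were not run, so the 14 are no matched reference. How far the relation depended on that tumour stayed open, as did the relation itself. With shared arrays the correlation was 0.746 against 0.463 by reassignment, and the covariance 0.075 against 0.0163. With split arrays the covariance was 0.0695 against 0.00155. The need for the relation to hold without replicate 3 was added after these values were seen.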
